A study of Mus musculus with 8 samples.

How the data were processed

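Liver RNA from 8 wild-type C57BL/6J mice was measured by bulk RNA sequencing. Feeding a standard diet for 4 weeks gave the control group and the same time on a diet with 1% 3,5-diethoxycarbonyl-1,4-dihydrocollidine (DDC) gave the other, with 4 animals each. Per the labels' protocols, polyadenylated RNA was selected, second strands were made with dUTP, and paired reads came from an Illumina instrument. All samples carry the same batch label.

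The deposited gene counts are whole numbers, not normalized, for 55401 Ensembl genes, of which 21933 were at 0 in every library. The deposited FPKM values, for 33467 genes, are the authors' counts scaled by length and depth, and the counts beside them equalled those of the count matrix. Per the submitters' processing notes the tools were cutadapt, FastQC, HISAT2, StringTie and DESeq2, with no versions given, on the builds GRCm38 and mm10. Coordinates and gene symbols are those of the deposited table. Whether counting used strand is not given in the sources used here, so overlapping genes may share reads.

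The main test was edgeR 4.0.16 (R 4.3.3), with TMM scaling, filterByExpr, robust quasi-likelihood fits and Benjamini-Hochberg adjustment, two-sided, at an adjusted p of 0.05. It was fitted to the counts of all 8 libraries with no covariate. Values are TMM-scaled CPM, the count of a gene over the scaled library total, as mean ± SD with n = 4 per group, and fold changes are DDC over control. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Library depth ran from 61179103 to 81664058 counts, and intervals from it cover counting error only. Depth and composition were compared by exact two-sided permutation over the 70 assignments of 4 against 4, whose smallest p is 0.0286.

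Before the data were examined, 44 gene lists with 709 members were fixed from textbook knowledge, of which 43 had at least 3 of their members tested. Each was compared with all other genes by camera in limma 3.58.1 with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were alternatives. Genes were chosen by a rule fixed at the same time. It takes Fech and Alas1, and the 10 largest rises and 10 largest falls among called genes that reach 10 CPM in the higher group, separate the groups fully and have an established symbol. It adds up to 4 called members of each list at 1 CPM or more, plus the largest called member that moved against its list. Where no member was called, it takes the most abundant one. The rule gave 188 genes, of which the text names a part. Other genes singled out were chosen after their values were seen.

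The fits were checked on simulated counts for this comparison with 200 genes changed among 18908 tested. They recovered 16 of 50 genes changed 1.5-fold, 39 of 50 changed 2-fold, 39 of 50 changed 4-fold and 34 of 50 changed 0.5-fold. Of 133 calls, 5 were false. The criterion first set, recovery of 80% of the 4-fold genes, was missed at 78%, and after that result was seen the criterion was replaced by unbiased fold changes and at most 10% false calls. Among 44 simulated lists the changed one was called and 0 unchanged ones were. Simulated genes were drawn independently, whereas the estimated correlation within a real list reached 0.946, for the male-biased list. False list calls among correlated genes were therefore not tested. Nor were false calls when as many genes change as in these data.

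Alternatives fixed beforehand were DESeq2 size factors, upper-quartile scaling, totals without the 20 most abundant genes, other filters, DESeq2 1.42.0, limma voom, limma on log2 FPKM with pseudocounts of 0.1 and 1, a test against a fold of 1.5, leaving out each library and a replicate block. Library totals alone and the omission of library pairs were added after seeing the data. Members of the Mup, Sult2a, Gsta, Gstm, Saa, Cyp2, Cyp4a, Ugt2b, Hspa1, hemoglobin and Serpina families share sequence, so counting could split their reads and their values are uncertain. Libraries of one group differed by more than sampling noise, so none was counted as a duplicate.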

Results

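The libraries asked how liver transcripts differ between mice fed DDC, a porphyrinogenic compound used to model cholestasis and biliary fibrosis, and mice fed a standard diet. Control libraries held 63171820 ± 1610097 counts (SD, n = 4) and DDC libraries 71969363 ± 7637973 (n = 4), exact permutation p = 0.0857. Controls 1 to 4 held 64136830, 62602395, 64768950 and 61179103 counts, and DDC 1 to 4 held 63312756, 69784016, 81664058 and 73116621. DDC livers had 20894 ± 786 genes with at least 10 counts against 18147 ± 125 in controls (exact permutation p = 0.0286, n = 4 each). This threshold was not scaled to depth, so the deeper DDC libraries enlarge the difference. DDC 1, with a depth inside the control range, had 19828 such genes, against 17966 to 18249 in controls, and DDC 3, the deepest, had 21615. The 20 most abundant genes took 21.8% ± 0.593 of DDC counts and 24.5% ± 0.880 of control counts (exact permutation p = 0.0286, n = 4 each). Alb, which encodes serum albumin, took 6.19% ± 0.671 of DDC counts and 9.37% ± 1.10 of control counts (exact permutation p = 0.0286, n = 4 each). A p of 0.0286 is the smallest that 4 against 4 allows, and over the 6 measures of depth and composition it became 0.0429 after Benjamini-Hochberg adjustment. The first principal component held 72.5% of the variance and separated the groups.

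**Figure D1:**
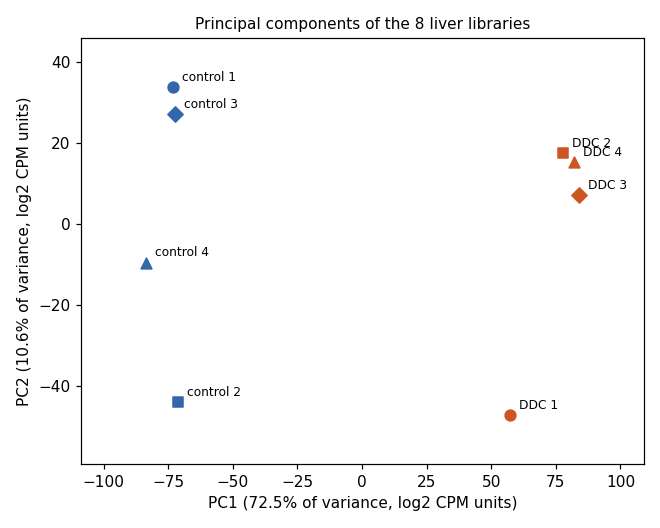
Principal components of log2 CPM over 14824 genes, with PC1 on the horizontal and PC2 on the vertical axis and 1 point per library, blue for control and orange for DDC, and a marker shape per replicate number. All 4 DDC libraries lie between 57.4 and 83.8 on PC1 and all 4 controls between -83.7 and -71.4.

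DDC livers carried more monocyte-derived macrophage, fibrillar matrix and chemokine transcripts and less of the pericentral, periportal, secreted protein and fatty acid oxidation transcripts of hepatocytes than control livers. Gpnmb, a glycoprotein of lipid-laden macrophages, rose 122-fold, from 2.85 ± 1.25 to 347 ± 36.9 CPM (SD, n = 4 each). Col1a1, the main fibrillar collagen chain, rose 16.2-fold from 10.7 ± 3.07 to 174 ± 33.6 CPM. Cyp2e1, a pericentral cytochrome P450, fell 8.48-fold, from 12383 ± 1008 to 1460 ± 326 CPM. Across 19535 tested genes, 11098 differed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 5893 higher and 5205 lower in DDC. List members said to rise or fall passed this same threshold, so their counts are to be read beside these shares of all genes. Changes of at least 2-fold numbered 3815 upward and 1728 downward. The groups did not overlap for 10276 genes, or 52.6% of those tested, against 2.86% by chance. The direction of the count depended on scaling: TMM factors ran from 0.792 to 0.815 in controls and from 1.21 to 1.27 in DDC. With library totals alone 11501 genes were higher and 1750 lower, so 86.8% of calls were higher against 53.1% with TMM, and the median log2 fold change of all genes moved from 0.073 to 0.70.

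Ferrochelatase (Fech), the last enzyme of heme synthesis, fell 2.34-fold, from 222 ± 4.55 to 94.9 ± 5.47 CPM (log2 fold change -1.23, SE 0.06, edgeR adjusted p = 2.26e-07). The gene, ENSMUSG00000024588, lies on chromosome 18 at 64452914 to 64490251 in GRCm38. Among 8 heme synthesis enzymes, 6 fell and 1 rose. The list was lower relative to other genes (camera adjusted p = 0.00464, or 0.066 with an estimated correlation). Cpox fell 2.74-fold and Urod 1.93-fold. Alas1, the first and rate-limiting enzyme (ENSMUSG00000032786, chromosome 9, 106233455 to 106248654), rose 1.39-fold (SE 0.15 on the log2 scale, adjusted p = 0.0232), a call that ended when 5 of the 8 libraries were left out in turn, with adjusted p from 0.0568 to 0.0673. With library totals alone the mean log2 fold change of the 8 enzymes was 0.043 and the list did not pass (camera adjusted p = 0.0531). Of 16 genes of heme breakdown and iron handling, 10 rose and 3 fell, and the list did not pass (camera adjusted p = 0.0878). It passed as higher with library totals alone and without the 20 most abundant genes in the totals (adjusted p = 0.00897 and 0.0106). The same held without a count filter, with the replicate block and with fry (adjusted p = 0.0131, 0.0492 and 5.3e-05). Hmox1, which degrades heme, rose 4.46-fold, and Abcb6, a porphyrin transporter, fell 2.71-fold.

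**Figure D2:**
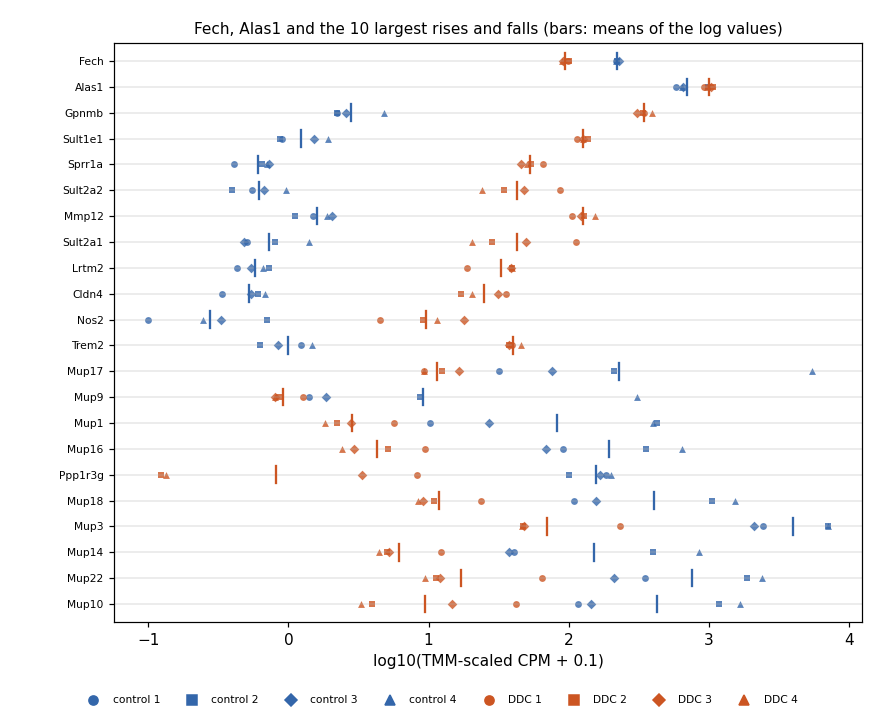
TMM-scaled CPM on a log10(CPM + 0.1) axis for Fech, Alas1 and the 10 largest rises and falls, 1 point per library, with bars at the means of the log values. Gpnmb is 2.11 to 4.71 CPM in controls and 306 to 396 CPM in DDC, while Mup17 is 5453 CPM in control 4 and 31.8 to 211 CPM in the other controls.

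The 10 largest rises, each with its groups fully apart, were Gpnmb, Sult1e1, Sprr1a, Sult2a2, Mmp12, Sult2a1, Lrtm2, Cldn4, Nos2 and Trem2. Sult1e1, an estrogen sulfotransferase, rose 105-fold to 126 ± 9.23 CPM (n = 4). Sprr1a, a cornified envelope protein, rose 102-fold to 53.6 ± 8.43 CPM. Without DDC 1 the log2 fold change of Sult2a1 went from 6.25 to 5.54, and without control 2 that of Nos2 went from 5.43 to 6.39; Nos2 lost its call with limma voom (adjusted p = 0.0502). Mmp12, a macrophage elastase, rose 82.9-fold, and Trem2, a macrophage lipid receptor, rose 42.5-fold to 39.9 ± 3.97 CPM. Of the 10 largest falls, 9 were major urinary proteins, male-biased secreted proteins encoded in a family on chromosome 4 whose reads may be shared. The 2 largest, Mup17 and Mup9, were 5453 and 305 CPM in control 4 and at most 211 and 8.53 CPM in the other controls. Their log2 fold changes went from -6.94 and -6.57 to -3.18 and -2.21 without control 4, and each lost its call when any 1 DDC library was left out, with adjusted p from 0.0534 to 0.0663 for Mup17 and from 0.0805 to 0.0882 for Mup9. Without controls 2 and 4, an omission chosen after seeing the data, Mup9 was at -0.88 and Mup10 at -3.05. Neither passed there (edgeR adjusted p = 0.0769 and 0.079). With the replicate block Mup17, Mup9, Mup1, Mup14 and Mup10 lost their calls (adjusted p from 0.0616 to 0.216). Mup9 and Mup1 also lost theirs with limma voom (adjusted p = 0.284 and 0.0924). Mup3 fell 50.5-fold, from 4692 ± 2796 to 92.9 ± 91.8 CPM, and its log2 fold change went from -5.66 to -6.67 without DDC 1. The other was Ppp1r3g, which fell 57.1-fold from 162 ± 43.2 CPM and was 8.13, 0.024, 3.27 and 0.033 CPM in DDC 1 to 4. Its log2 fold change went from -5.84 to -7.17 without DDC 1, and whether counts of an overlapping transcript affect it was not tested.

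Fibrillar matrix and matrix remodelling genes rose in 31 of 33 cases, with 1 fall (camera adjusted p = 3.98e-26). Timp1, an inhibitor of metalloproteinases, rose 16.9-fold and Thbs1 13.6-fold. Fn1, fibronectin, was the member that fell, 1.52-fold from 1912 ± 122 to 1259 ± 50.4 CPM, and had a log2 fold change of 0.019 with library totals alone. Of 21 stellate cell and fibroblast markers, 9 rose, 11 did not pass, and Colec11 fell, with a log2 fold change of -0.45 that became 0.17 with library totals alone (camera adjusted p = 0.0255; adjusted p = 0.195 with an estimated correlation). Pdgfrb rose 3.43-fold. The list call ended without DDC 1 (adjusted p = 0.0879) and with library totals alone (adjusted p = 0.0531). Acta2, chosen after its values were seen, was 56.2 CPM in control 2 and 4.09 to 6.11 CPM in the other controls and did not pass (adjusted p = 0.831). Hippo-YAP target genes rose in 10 of 14 cases with 1 fall, Axl 4.91-fold and Ccn2 3.17-fold (camera adjusted p = 0.00253).

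Bile duct and ductular markers rose in 17 of 21 cases and none fell (camera adjusted p = 8.14e-06; adjusted p = 0.278 with an estimated correlation). Cldn4 rose 59.2-fold and Cftr, a chloride channel of cholangiocytes, 14.7-fold. Krt19, chosen after its values were seen, did not pass (adjusted p = 0.476) and was 60.7 CPM in control 2 against 26.7 to 46.5 CPM in DDC. Control 2 also had the highest score of this list among the controls, 0.93 against -0.62 to -0.10 in the others. The missed call therefore does not show that Krt19 was unchanged. The list's mean log2 fold change was 2.27 with all libraries and 2.82 without control 2. Fetal liver and progenitor genes rose in 10 of 11 cases (camera adjusted p = 0.00143; adjusted p = 0.195 with an estimated correlation). H19 was 569 CPM in DDC 1 and 7.24 to 11.2 CPM in the other 3, and its log2 fold change went from 5.23 (adjusted p = 0.0438) to 1.20 (adjusted p = 0.0181) without DDC 1. Leaving out any single control ended the H19 call, with adjusted p from 0.0749 to 0.1005. Notch pathway genes rose in 8 of 13 cases, Jag1 2.55-fold, and the list did not pass in the main test (camera adjusted p = 0.085). It passed as higher without a count filter, with the replicate block and with fry (adjusted p = 0.00774, 0.0492 and 0.000372).

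Monocyte-derived macrophage markers rose in 17 of 17 cases (camera adjusted p = 1.34e-31), with Cx3cr1 up 20.5-fold and Itgax 19.1-fold. Kupffer cell markers rose in 9 of 12 cases with 1 fall (camera adjusted p = 0.000916; adjusted p = 0.227 with an estimated correlation). Marco, a scavenger receptor, rose 10.9-fold and was 50.5 CPM in control 4 against 12.5 to 15.3 CPM in the other controls, and its log2 fold change went from 3.44 to 4.14 without control 4. Chemokine and cytokine genes rose in 23 of 24 cases (camera adjusted p = 3.79e-15). Cxcl2 rose 18.2-fold and Tnf 18.0-fold. Ccl7 had 0 counts in the controls and 616 in DDC, at least 116-fold higher over a floor of 3 counts for the 4 controls together. Neutrophil markers rose in 8 of 14 cases (camera adjusted p = 0.0161; adjusted p = 0.346 with an estimated correlation). Csf3r rose 7.36-fold, but the mean score of the list was -0.71 in DDC 1 and 1.28 to 1.54 in DDC 2 to 4, and the list did not pass with library totals alone (adjusted p = 0.186). T and NK cell markers rose in 7 of 14 cases without a list call (camera adjusted p = 0.0866). The T and NK list passed as higher without a count filter, with the replicate block and with fry (adjusted p = 0.00774, 0.0394 and 0.000212). B and plasma cell markers fell in 5 of 10 cases and rose in 1, Cd22, without a list call (camera adjusted p = 0.443). Sinusoidal endothelial markers rose in 9 of 12 cases (camera adjusted p = 0.0234; adjusted p = 0.296 with an estimated correlation), Stab1 2.57-fold, a call lost without DDC 1 (adjusted p = 0.082). Vascular and capillary endothelial markers rose in 5 of 12 cases (camera adjusted p = 0.276) and mesothelial markers in 3 of 8 (camera adjusted p = 0.205). These member counts alone do not set the lists apart, since 5893 of all 19535 tested genes rose. Fry called both lists higher (adjusted p = 0.00578 and 0.00549). In the main test 0 of 3 adipocyte markers passed (camera adjusted p = 0.939), with Fabp4 at 20.1 CPM in controls and 23.3 CPM in DDC. Fabp4 passed as higher with library totals alone, without the 20 most abundant genes in the totals and in the 3 FPKM fits (adjusted p from 0.00333 to 0.00879). Only 2 pancreas acinar markers were tested, and Cela1 was 7.69 CPM in controls and 4.16 CPM in DDC (adjusted p = 0.0151, but 0.373 with library totals alone and 0.0527 without DDC 3).

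Cell cycle genes rose in 23 of 25 cases (camera adjusted p = 1.29e-13), with Ccnd1, cyclin D1, up 7.07-fold and Cdc20 up 7.56-fold. NRF2 target genes rose in 14 of 22 cases with 2 falls (camera adjusted p = 1.52e-06; adjusted p = 0.111 with an estimated correlation). Gsta1 rose 24.1-fold and Slc7a11 10.1-fold, while Me1 fell 3.14-fold. Of 14 p53 target genes 9 rose and 3 fell (camera adjusted p = 0.125). The p53 list passed as higher with library totals alone and without the 20 most abundant genes in the totals (adjusted p = 0.0412 and 0.0437). It also did so without a count filter and with fry (adjusted p = 0.0421 and 4.17e-06). Of 20 genes of the ER stress and integrated stress response 12 fell and 3 rose (camera adjusted p = 0.0808), Herpud1 falling 3.81-fold and Atf3 rising 4.94-fold. The ER stress list passed as lower without control 2 and without control 4 (adjusted p = 0.0366 and 0.0396). It also did so without a count filter, with the replicate block and with fry (adjusted p = 0.00684, 0.0448 and 2.48e-05). Of 14 keratin and Mallory-Denk body genes 4 rose and 7 fell, and the list's median of -0.45 differs in sign from the camera direction (adjusted p = 0.462). Fry called this list higher (adjusted p = 0.027). Krt8 rose 5.71-fold and Hspa1b fell 13.8-fold. Immediate early genes rose in 3 of 12 cases, Egr2 16.3-fold, with a median of -0.39 and a mean of 0.28 (camera adjusted p = 0.577). List scores were 0.85, -0.77, 0.75 and -0.83 in controls 1 to 4. In omissions chosen after seeing the data this list passed as higher without controls 1 and 3 and as lower without controls 2 and 4 (adjusted p = 0.00171 and 0.00692).

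Bile acid synthesis genes fell in 10 of 14 cases with 1 rise (camera adjusted p = 0.000414). Cyp7b1 fell 15.5-fold, Cyp8b1, the sterol 12-alpha-hydroxylase, 12.9-fold, and Acox2 rose 1.72-fold. The log2 fold change of Cyp8b1 went from -3.69 to -3.01 without control 4 and to -4.40 without DDC 1. Of 12 bile acid uptake and canalicular transporters 9 fell and 1 rose (camera adjusted p = 6.57e-05; adjusted p = 0.0927 with an estimated correlation). Slc10a1, the sodium-dependent bile acid uptake transporter, fell 3.98-fold and Slco1b2 4.15-fold. Genes of basolateral export and the FXR pathway fell in 7 of 10 cases and rose in 2, without a list call in the main test (camera adjusted p = 0.176). The list passed as lower without a count filter and with fry (adjusted p = 0.0237 and 1.10e-05). Abcc4, a basolateral export pump, rose 9.69-fold and Slc51b 6.49-fold, the latter with a log2 fold change that went from 2.70 to 3.87 without control 1.

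Hepatocyte secreted proteins fell in 20 of 20 cases (camera adjusted p = 1.77e-13), Apoa2 3.70-fold and Plg 2.76-fold. Pericentral genes fell in 13 of 20 (camera adjusted p = 4.48e-09), with Glul, glutamine synthetase, down 7.42-fold. Periportal genes fell in 14 of 17 with 1 rise (camera adjusted p = 3.10e-10), G6pc 5.48-fold. Urea cycle genes fell in 8 of 8 (camera adjusted p = 0.000119; adjusted p = 0.0972 with an estimated correlation), Otc 2.81-fold. Fatty acid oxidation and ketogenesis genes fell in 22 of 23 (camera adjusted p = 2.20e-20), Acaa1b 6.98-fold. Fatty acid and triglyceride synthesis genes fell in 13 of 17 with 2 rises (camera adjusted p = 4.17e-05; adjusted p = 0.278 with an estimated correlation), Lpin1 8.81-fold. The fatty acid synthesis list scored 0.48, -0.27, 0.37 and -0.58 in controls 1 to 4, and its mean log2 fold change was -0.82 without controls 1 and 3 and -1.66 without controls 2 and 4, omissions chosen after seeing the data. Liver transcription factors fell in 14 of 15 (camera adjusted p = 6.94e-07), Ppara 5.29-fold and Nr5a2 2.43-fold. Circadian clock genes fell in 12 of 18 (camera adjusted p = 8.48e-06), Nr1d1 2.76-fold. Cholesterol synthesis genes rose in 7 of 22 and fell in 3 (camera adjusted p = 0.39), Hmgcs1 rising 4.26-fold, and this list passed as higher without controls 1 and 3 (adjusted p = 0.025).

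Xenobiotic CYP and conjugating enzymes fell in 13 of 24 and rose in 5 (camera adjusted p = 0.00141; adjusted p = 0.331 with an estimated correlation), with Cyp2b10 up 11.1-fold and Ces1d down 6.35-fold. The xenobiotic list scored 0.43, -0.52, 0.52 and -0.44 in controls 1 to 4 and -0.21 to -0.53 in DDC. In omissions chosen after seeing the data its mean log2 fold change went from -0.56 to 0.14 without controls 1 and 3 and to -0.82 without controls 2 and 4, with a downward camera call in both (adjusted p = 0.00296 and 4.33e-10). Acute phase proteins fell in 12 of 22 and rose in 4 (camera adjusted p = 0.0207; adjusted p = 0.346 with an estimated correlation), a call lost without DDC 1 (adjusted p = 0.0963) and with a filter of 1 CPM in 4 libraries (adjusted p = 0.057). Saa1 fell 4.09-fold and Lcn2 rose 10.1-fold. Growth hormone and STAT5 pathway genes fell in 7 of 13 with 2 rises (camera adjusted p = 0.00887; adjusted p = 0.0748 with an estimated correlation), Ghr 5.32-fold, a call lost without control 2 (adjusted p = 0.0664). Male-biased liver genes fell in 15 of 16 (camera adjusted p = 0.000324; adjusted p = 0.418 with an estimated correlation), with list scores of -1.33 and -1.32 in controls 1 and 3 and 1.25 and 1.41 in controls 2 and 4. Female-biased liver genes fell in 5 of 17 and rose in 2 (camera adjusted p = 0.462), with list scores of 1.22, -1.17, 0.93 and -0.98 in controls 1 to 4. The mean log2 fold change of this list was -1.17 without controls 2 and 4 (adjusted p = 0.0125), 1.68 without controls 1 and 3 (adjusted p = 0.068) and 0.37 without control 1 (adjusted p = 0.795). Erythroid genes fell in 7 of 9 (camera adjusted p = 0.0476; adjusted p = 0.195 with an estimated correlation), Alas2 8.31-fold, a call lost without control 2 (adjusted p = 0.0527) and with a filter of 1 CPM in 4 libraries (adjusted p = 0.0799). Mitochondrially encoded transcripts fell in 11 of 13 (camera adjusted p = 0.00994; adjusted p = 0.502 with an estimated correlation), and with library totals alone their mean log2 fold change was 0.066 and the list did not pass (adjusted p = 0.0526).

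**Figure D3:**
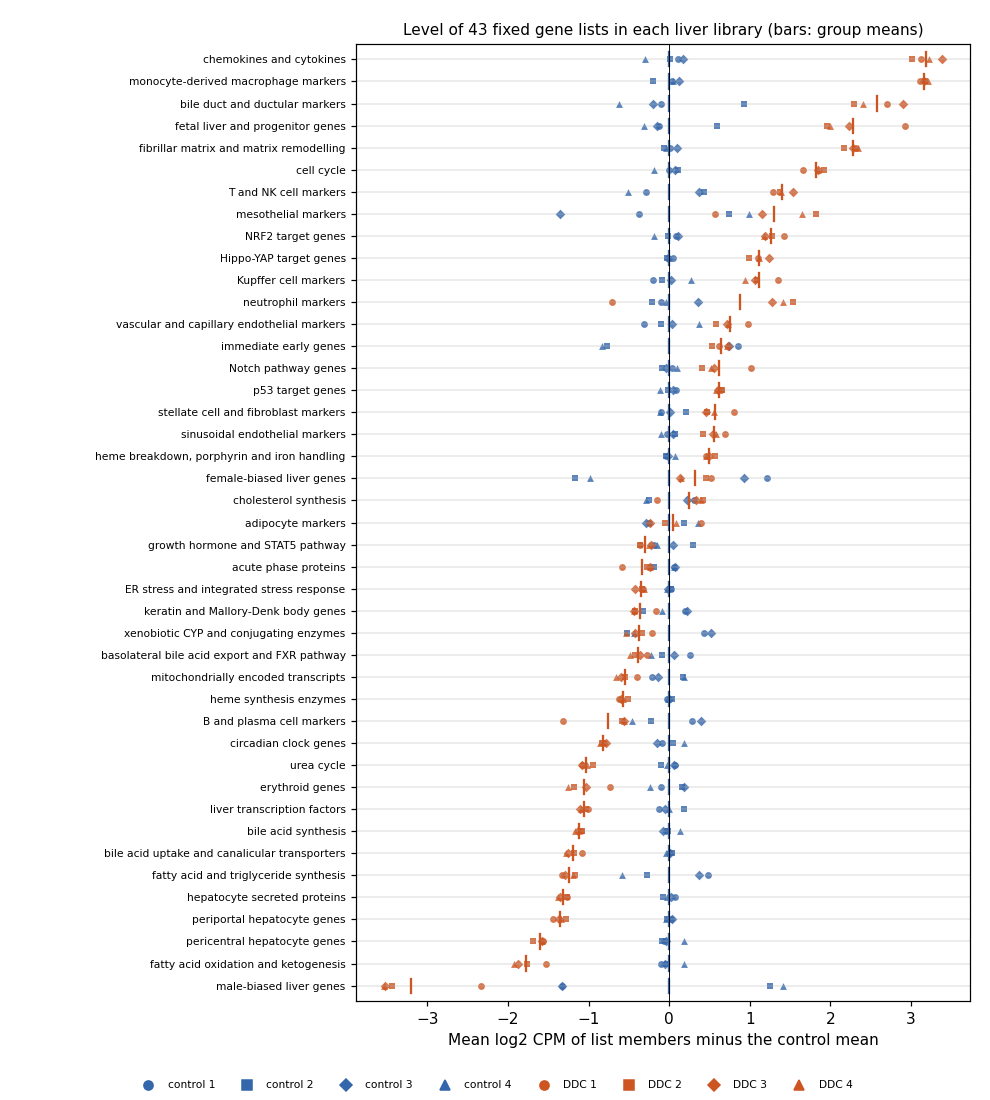
Mean log2 CPM of each of 43 gene lists minus the control mean, 1 point per library, blue for control and orange for DDC, with bars at group means. Monocyte-derived macrophage markers lie between 3.11 and 3.21 in DDC and between -0.21 and 0.12 in controls, and male-biased genes are split within the controls.

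In all, 29 of 43 lists passed with the preset correlation, 12 higher and 17 lower, and 12 passed with an estimated correlation. These 12 were bile acid synthesis, fibrillar matrix, monocyte-derived macrophage, chemokine, pericentral, periportal, hepatocyte secreted protein, cell cycle, Hippo-YAP, fatty acid oxidation, liver transcription factor and circadian clock lists. Adjusted over the list alone, 266 members rose and 263 fell, against 261 and 258 over all genes. With library totals alone the mean log2 fold change turned positive for 9 lists, the heme synthesis and mitochondrial lists given above and the basolateral export, xenobiotic, ER stress, keratin, acute phase, female-biased and growth hormone lists, at 0.16, 0.058, 0.25, 0.22, 0.28, 0.33 and 0.15, while the camera direction, relative to other genes, stayed the same for these 9. The adipocyte list had a median of 0.042 and a mean of 0.032 and a downward camera direction.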

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

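The tests of the male-biased genes and of control library 2 were chosen only after the results were seen; the other tests were fixed beforehand. Within a group of 4, a library was picked out where its gap to the nearest other one was large beside the whole range. Chance picks out about 1 in 20 groups, or 23.6 of the 472 tested, and 47 were picked out, 28 of them for DDC 1.

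In DDC 1, genes set apart above the other 3 DDC libraries, by a gap that was large beside the range whatever its fold, were H19 (569 CPM), Cyp2b10 (543), Mup3 (231), Mup22 (64.1), Serpina6 (55.9), Pdgfrb (51.6), Sult2a8 (32.1), Mup18 (23.6), Alas2 (15.3), Hspb1 (12.7), Slco1a1 (12.7), Mup14 (12.1), Esrrg (1.34) and Mup9 (1.17). Genes set apart below were Lcn2 (268 CPM), Id3 (67.4), Mvd (27.5), Lrtm2 (18.8), Atf3 (14.0), Dbp (13.9), Tgfb2 (7.96) and Acot3 (3.39). By list score DDC 1 was low for B and plasma cell markers (-1.32), neutrophil markers (-0.71), acute phase proteins (-0.59) and cholesterol synthesis (-0.15), and high for male-biased genes (-2.33) and keratin genes (-0.16).

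In control 4 Mup17 (5453 CPM), Mup9 (305), Saa1 (213), Marco (50.5), Lyve1 (7.39) and Gpnmb (4.71) were set apart above the other controls. In control 2 Cd44 (27.9 CPM) and Socs2 (20.6) were high, and Trp53inp1 (176), Cpox (109) and the acute phase score (-0.19) were low. Single values stood apart for Abcb6 in control 1 (86.7 CPM, low), Ccl4 in control 3 (0.133, high), Ppara (26.3, high), Fcgr2b (56.7, low) and the pericentral score (-1.69, low) in DDC 2, Igfbp2 (146, high) and Cftr (12.1, high) in DDC 3, and Slc27a5 in DDC 4 (312, low).

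Of 10 marker lists of other cell types, 6 passed as higher in DDC livers, and with an estimated correlation only the monocyte-derived macrophage list did (adjusted p = 0.00105, against 0.195 to 0.659 for the others). A lower share of hepatocyte RNA would raise them alike, but the medians of 10 lists spanned 4.30 on the log2 scale, from -1.09 for B and plasma cells to 3.21 for monocyte-derived macrophages, more than in any of 100000 shuffles of members (permutation p = 1e-05, the smallest they can give). The shuffles treat members as independent, although the estimated correlation was 0.48 in the ductular list, so this p does not measure the spread between animals. The B and plasma cell list at the low end did not pass (camera adjusted p = 0.443). In the DDC libraries macrophage scores were 3.11 to 3.21 and sinusoidal endothelial scores 0.42 to 0.69. That unequal rise argues against a lower hepatocyte share as the whole cause. Attached pancreas or fat did not reach the difference of 10 CPM set beforehand, whereas the mesothelial list did, with DDC sums of 23.2 to 31.9 CPM, control sums of 7.31 to 11.4 CPM and group means 17.6 CPM apart, mostly through Msln (means of 5.12 and 19.1 CPM). Attached mesothelium therefore stays open for that list, and a response of the liver cells to DDC stays open as a hypothesis.

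Male-biased genes were low in controls 1 and 3 and high in controls 2 and 4, Mup7 at 184, 230, 3289 and 2791 CPM in controls 1, 3, 2 and 4. Female livers among the controls are argued against by Y-linked transcripts, whose sum in the lower of controls 1 and 3 was 112% of the mean of the other 6 libraries. DDC liver RNA in these libraries is argued against by macrophage markers, at a median of 11.01% of the DDC mean in control 3, 9.62% in control 1, 10.02% in control 2 and 11.6% in control 4. No biological explanation was tested, and all libraries share 1 batch label. Without controls 2 and 4 the mean log2 fold change of the male-biased list was -1.73, against -3.68 with all libraries. In that fit the members Mup7 and Hsd3b5, at -1.66 and -0.71, lost their calls (edgeR adjusted p = 0.091 and 0.41).

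Control 2 held more of several mucin and smooth muscle transcripts than the other controls, with Dmbt1 at 1473 CPM against 4.81 to 10.7 CPM. A candidate source is the wall of the gallbladder or a large bile duct, a tissue no label names. Of 10 measured mucosal epithelium markers 9 were highest in control 2 among the controls, but of 14 smooth muscle markers, 2 of them also in the stellate list, only 9, or 64.3%, below the 75% the test required of both lists. The median log2 ratio of control 2 to the mean of the other controls was 2.22 for the mucosal list and 1.25 for the smooth muscle list. The most abundant markers were Lgals4 at 75.3 CPM and Mylk at 75.5 CPM, both also present in the other controls. Ctrb1, a pancreatic protease gene, was at 11.6 CPM in control 2 against 0 to 0.136 CPM in the other controls. Among the other acinar markers, Cela1 was also highest there, at 11.7 CPM against 5.47 to 7.83 CPM. Pnlip, Clps and Try5 were at 0 in control 2, and Cela2a was at 0.314 CPM against 0 to 0.893 CPM. The source therefore stays open, no biological explanation was tested, and the mean log2 fold change of the ductular list was 2.82 without control 2 against 2.27 with all libraries.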

How the results depend on the processing

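The settings that leave out library pairs, and library totals alone, were chosen after seeing the data. Scaling changed directions most. Higher and lower genes numbered 11006 and 1914 with totals without the 20 most abundant genes (6415 and 733 by at least 2-fold), 11501 and 1750 with library totals alone (6705 and 688), 11757 and 1818 with limma on log2(FPKM + 0.1) (6350 and 674), 11801 and 1804 on log2(FPKM + 1) (2364 and 390), and 12283 and 1745 on log2(FPKM + 0.1) without a filter (6464 and 666). Of genes called by both fits, 1170 had the opposite direction with library totals alone, and 0 with DESeq2 size factors or upper-quartile scaling. A test against a fold of 1.5 called 5436 genes, 3316 higher and 2120 lower, by its construction. Colec11 turned to a log2 fold change of 0.12 without the 20 most abundant genes, 0.17 with library totals and 0.18, 0.17 and 0.18 in the 3 FPKM fits, and Fn1 to 0.019 with library totals and 0.016 in the 3 FPKM fits. Lists called fell to 12, 5 higher and 7 lower, with an estimated correlation. Fry called 38 lists, 19 higher and 19 lower, and so added 9. The heme breakdown, T and NK cell, vascular endothelial, keratin, p53, Notch and mesothelial lists were added as higher. The basolateral export and ER stress lists were added as lower. The immediate early list passed in opposite directions, at -0.15 without controls 2 and 4 (adjusted p = 0.00692) and 1.38 without controls 1 and 3 (adjusted p = 0.00171), against adjusted p from 0.398 to 0.764 with 1 library left out; the cause was not tested. The share of the 5 most abundant genes differed by -1.43 points (exact permutation p = 0.0571), the cause was not tested. Leaving out 1 library gave 9632 to 11760 genes and 26 to 30 lists; 13 of 188 genes chosen by the rule lost their call in some such fit (Alas1, Cd3g, Cela1, H19, Hsd3b5, Ighm, Lrrn4, Mup17, Mup7, Mup9, Nr0b2, Pnpla3 and Socs2), and 175 had the same result in all 8. The replicate block gave 9464 genes and 33 lists. Replicate numbers are not said to pair the animals. Correlations of deviations between libraries of the same number were -0.26, -0.24, 0.036 and -0.046, and no library matched its own number best. These values gave no sign of pairing but cannot exclude it. Of the 35 splits of the 8 libraries only the real 1 gave as many genes (11098, highest other 1). That share, 0.0286, is the smallest that 35 splits can give, so it argues against chance without excluding it. Every other split puts control and DDC libraries on the same side, which widens the spread there and leaves few genes to call. For lists 5 of 35 gave at least 29, up to 31, so the list count alone does not exclude chance; the other 4 exchange 1 library of each group and keep most of the real contrast, and splits that exchange 2 gave at most 11. Depth limits the fold of Ccl7, at 0 counts in the controls, to a bound of at least 116-fold.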

Other observations

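Pathways of the deposited annotation, a test chosen after seeing the data, added mitochondrial and amino acid metabolism. Of 304 KEGG pathways with 10 to 300 tested genes, 129 passed camera with the preset correlation, 74 higher and 55 lower, but only 2, phagosome and tuberculosis, with an estimated correlation. Oxidative phosphorylation genes fell in 96 of 125 cases and rose in 13 (adjusted p = 8.32e-10; adjusted p = 0.287 with an estimated correlation). Citrate cycle genes fell in 28 of 33 (adjusted p = 1.52e-07; adjusted p = 0.226 with an estimated correlation). Valine, leucine and isoleucine degradation genes fell in 39 of 51 (adjusted p = 3.54e-15; adjusted p = 0.0566 with an estimated correlation). Tryptophan metabolism genes fell in 28 of 39 (adjusted p = 3.40e-11; adjusted p = 0.0566 with an estimated correlation). Phagosome genes rose in 83 of 143 and fell in 31 (adjusted p = 1.15e-07; adjusted p = 0.0397 with an estimated correlation). Pathways were tested with TMM scaling only. Median log2 fold changes were -0.72 for oxidative phosphorylation and -0.81 for the citrate cycle. With library totals alone the median of all tested genes moved from 0.073 to 0.70, so these counts of falls may depend on scaling.

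Controls 1 and 3 also differed from controls 2 and 4 in genes chosen after their values were seen. Fos was 83.3, 5.59, 67.6 and 5.45 CPM in controls 1 to 4. Fasn, fatty acid synthase, was 1101, 249.7, 997 and 157 CPM in these libraries. In DDC 1 the neutrophil granule gene Ngp was 1.92 CPM, against 14.9 to 28.1 CPM in the other DDC libraries, and the interferon-induced gene Ifit3 was 32.5 CPM, against 10.3 to 13.2 CPM.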
